A study of Mus musculus with 11 samples.

How the data were processed

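Genomic DNA of 11 mammary tumours from Pik3ca H1047R mice of mixed FVB/N and B6 strain was hybridised against liver DNA of the same animal on Agilent mouse genomic arrays, with the tumour labelled in Cy5 (red) and the liver in Cy3 (green), per the labels. Per the submitters' processing notes, images were read with Agilent Feature Extraction 10.5.1.1 and values were made in Partek, for which no version is given. Per the file headers, the 4 arrays of tumours 4, 7, 9 and 11 were read with Feature Extraction 11.0.1.1 instead, and all arrays use probe positions of mouse build mm9. The arrays lie on 3 slides, slide 1 with tumours 2, 3 and 8, slide 2 with tumours 4, 7, 9 and 11, and slide 3 with tumours 1, 5, 6 and 10.

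The deposited scanner files give, per spot, the intensity of both channels after background subtraction and a linear dye normalization by the authors' software, and raw medians of spot and background intensity. The LogRatio column of the deposited files is the log10 of the processed red over green signal, except at 16 to 2827 spots per array where the column holds 0. Tumour 2 had the 2827 spots, and the next highest number was 359 in tumour 4. The ratio of processed signals was used at these spots, and in tumour 2 it lay up to 0.860 (log2) from 0. The authors' value table holds the mean LogRatio of each probe converted to log2, not centred further, with column medians from -0.0490 to 0.0213. The file headers give a signal to background ratio of the negative control spots, from 1.77 to 2.97 in green and from 1.70 to 3.10 in red. The share of spots not well above background in at least 1 channel ran from 0.0803% in tumour 6 to 12.8% in tumour 9. Each array has 174305 spots of genomic probes, none of them saturated.

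The log2 of processed red over processed green signal was averaged over the spots of each probe, spots marked as outliers were left out, and the median of the array was subtracted. This gave 170305 probes, of which 161460 are autosomal and 122 lie on chromosome Y and were left out of the segmentation. Segments were found per chromosome by exact optimal partitioning with a penalty of 2 times the noise variance times the natural logarithm of the number of probes, at least 5 probes per segment, and single probes beyond 4 SD of a running median of 11 probes pulled in to that limit. A segment of at least 10 probes with an absolute mean of at least 0.2 was called a gain or a loss. A chromosome with at least 80% of its probes in calls of 1 direction was called changed as a whole, and recurrence was counted over chromosomes with at least 50%. Focal changes were called segments of at most 10 Mb with an absolute mean of at least 0.6. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 and statmod 1.5.0.

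Gene values are means over the probes that the array annotation assigns to a gene, for 20690 gene names. No annotation on build mm9 beyond that of the array was at hand, and a gene table of a later build served only for current names and the order of neighbours. List genes without a probe of their own were read from the interval between their nearest neighbours on the array, if at most 2 Mb long. The array names no probe after an antigen receptor segment, so the loci were placed between flanking genes, a choice made after seeing the files (Tedc1 to Zfp386 for Igh, Il23r to Rpia for Igk, Hira to Lamp3 for Igl, Sall2 to Dad1 for Tcra/Tcrd, Moxd2 to Ephb6 for Tcrb, Amph to Stard3nl for Tcrg).

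The design has 1 group, so each test compares the tumours with their own livers. Chromosome means, gene lists, antigen receptor loci and Pik3ca were tested with exact two-sided sign-flip permutation tests over the 11 tumours, adjusted by Benjamini-Hochberg within each family. Genes with at least 3 probes (9300) were tested with limma (intercept, empirical Bayes, two-sided), called at an adjusted p below 0.05 and an absolute mean of at least 0.1. Recurrence of chromosomes was tested one-sided by reassigning altered autosomes within each tumour (100000 resamples), and recurrence of genes one-sided by shifting the calls of each tumour along the genome (1000 resamples), both against the maximum over the family. The percentile of a list's mean came from 10000 random lists of the same size. The 7 gene lists covered the PI3K, AKT and mTOR pathway, receptor tyrosine kinases, the RAS and MAPK pathway, amplified oncogenes and cell cycle genes, tumour suppressors, mammary lineage genes and genes of common fragile sites.

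The groups, tests, lists, thresholds and most alternatives were chosen before the data were examined. Genes were named by a rule that took Pik3ca, the list genes or the up to 3 strongest genes of each focal segment, list members in calls of at most 50 Mb or in most tumours, and the 5 highest and 5 lowest called genes of limma, up to 40 names with the focal ones first. The rule gave 222 names, 77 of them from focal segments, so the list members and limma genes named beyond the limit were chosen after their values were seen.

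The alternatives were normexp background correction (offset 50), centring on the mode, a loess fit on the GC content of the probe sequence (span 0.3), leaving out dim probes, keeping outlier spots, the authors' value table, a penalty factor of 1 or 4, circular binary segmentation, other thresholds (0.15 and 0.3), probe minimums (5 and 20 per segment, 1 and 5 per gene) and size limits, medians in place of means, a local baseline of 5 Mb on both sides, single slides, slide as a random block, and leaving out each tumour in turn. Alternatives chosen after seeing the data were removal of the first principal component of the within-segment residuals, leaving out tumours 9 and 11, and turning the sign of tumour 11, alone and together with the local baseline. The segmentation and limma were tested on simulated changes. At a height of 0.6, 100% of planted changes were found in the 9 tumours other than 9 and 11. Of 100 genes with a planted shift limma found 24 at 0.15 and 84 at 0.3, with 2 false calls. For this the signs of the residuals were flipped separately for each gene and tumour, which removes the correlation between genes. The 2 false calls therefore do not give the error rate of the test in the real data.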

Results

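Copy number was measured in 11 mammary tumours of mice that express the activated Pik3ca H1047R mutant, 1 tumour per animal, by hybridising each tumour DNA against liver DNA of the same animal on a mouse genomic tiling array. The tumours form 1 group (n = 11 animals, tumours 1 to 11) and lie on 3 slides of 3 to 4 arrays. Each array gave values for 170305 probes, and the log2 ratio of tumour over liver was read relative to the median of its array. The share of spots not well above background in at least 1 channel ran from 0.0803% in tumour 6 to 12.8% in tumour 9. The noise SD between neighbouring probes ranged from 0.13 in tumour 8 to 0.55 in tumour 9 and 0.51 in tumour 11, with a median of 0.18. With 1 array per animal, calls describe single arrays, and the number of arrays limits the precision of every mean. Tumour 11 ran opposite to several other arrays, and whether its channels were exchanged stays open, so values with its ratios turned, a setting chosen after seeing the data, stand beside several results. Positions are those of mouse build mm9.

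The first question was how much of each tumour genome differed from the liver. Tumour 8 had the most altered genome, with 35.3% of autosomal probes inside gains or losses, followed by tumour 7 with 31.6%, tumour 1 with 26.3% and tumour 2 with 22.0%. Tumour 3 had 12.02%, tumour 6 had 10.3%, tumour 4 had 7.45%, tumour 5 had 2.26% and tumour 11 had 0.324%. No autosomal change was called in tumours 9 and 10. Tumour 10 had a single call, a loss of 0.0762 Mb on chromosome X. Over all 11 tumours 153 gains and 159 losses were called, and the median share of altered autosomal probes was 10.3%. With the ratios of tumour 11 turned there were 149 gains and 163 losses. Losses outnumbered gains in tumour 8 (48 against 17), tumour 1 (37 against 16), tumour 7 (24 against 18, covering 25.7% and 5.89% of its autosomal probes) and tumour 4 (22 against 7, although gains covered 5.23% and losses 2.22% of its autosomal probes), while gains outnumbered losses in tumour 3 (35 against 10), tumour 2 (33 against 7), tumour 6 (20 against 6) and, in the labelled direction, tumour 11 (7 against 3). Tumours 5 and 10 had 1 loss each and no gain. Some short calls of tumours 4 and 11, which share a slide, lay at the same places with opposite signs. In tumour 2 the deposited LogRatio was 0 at 2827 spots, where the processed signals used here gave log2 ratios up to 0.860 from 0. Several probes in its gain on chromosome 6 shared the same centred ratio of 0.909. How far such spots add to the gains of tumour 2 was not tested. Changes of medium length and a height of 0.3 planted into the arrays were found in 0 of 3 cases in tumours 9 and 11 and in 95.9% of cases in the others. In tumours 9 and 11, long changes of that height were found in 24 of 25 cases, and short changes of 0.6 in 1 of 9. The totals depended on the segmentation penalty, with 516 gains and 734 losses at a lower penalty and 90 gains and 66 losses at a higher one. With normexp background correction there were 330 gains and 71 losses, so the balance of gains and losses depended on the processing too.

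**Figure D1:**
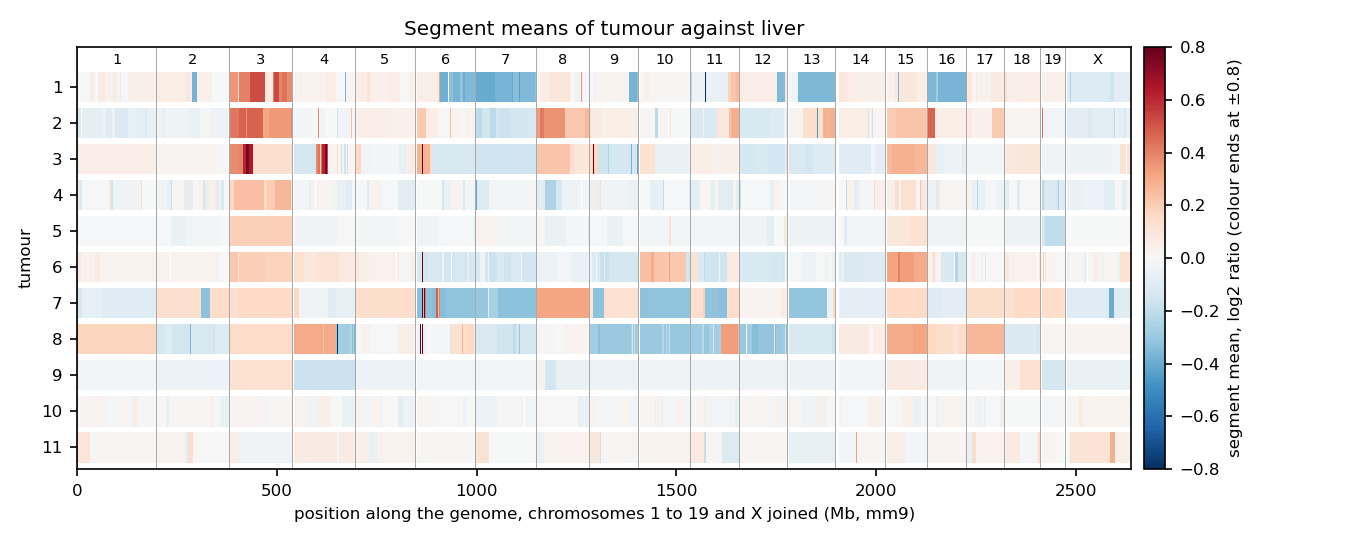
Segment means (log2 ratio of tumour over liver) along the genome for each of the 11 tumours, with gains and losses coloured by height. Gains over most of chromosome 15 are seen in tumours 2, 3, 6 and 8, and tumours 9 and 10 have no autosomal call.

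Whole-chromosome changes were called 21 times, as 11 gains and 10 losses. Chromosome 15 was gained as a whole in tumours 2, 3, 6 and 8, chromosome 3 in tumours 1, 2 and 4, and chromosome 8 in tumours 2 and 7. Single whole-chromosome gains were those of chromosome 10 in tumour 6 and of chromosome 17 in tumour 8. Chromosome 7 was lost in tumours 1 and 7, and chromosome 10 in tumours 7 and 8. Tumour 7 also lost chromosomes 6 and 13, tumour 8 lost chromosomes 9 and 12, tumour 1 lost chromosome 16 and tumour 5 lost chromosome 19. The loss on chromosome 19 in tumour 5, from 12325758 to 61319646, was the only call in that tumour and stood at the call threshold of 0.2, with a mean of -0.2004. The number of losses was 6 without tumour 7. Normexp background correction gave 22 gains, a threshold of 0.15 gave 17 gains, and a threshold of 0.3 gave 4 gains and 6 losses. Centring on the mode of the ratios in place of the median gave 12 gains and 10 losses. It moved the median ratio by -0.158 in tumour 7 and by 0.131 in tumour 8. Such shifts are large beside the threshold of 0.2 and means such as 0.31 for chromosome 8 in tumour 7. The similar totals therefore do not show that the same chromosomes were called.

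The next comparison asked whether the tumours share altered chromosomes beyond chance. A gain of at least 50% of chromosome 15 was present in 4 of the 11 tumours, more than random reassignment of each tumour's altered autosomes gave (one-sided permutation test with the maximum over autosomes, 100000 resamples, p = 0.0402). Chromosomes 3 and 8 were each gained over at least 50% of their probes in 3 tumours, which was within chance (p = 0.384 for each, same permutation test). No loss passed, with at most 2 tumours per chromosome (p = 0.989). The chromosome 15 call was lost without tumour 2, 3, 6 or 8 (permutation p = 0.185, 0.233, 0.231 and 0.183), after the GC fit (4 tumours, p = 0.0601), in the authors' value table (3 tumours, p = 0.406) and at a threshold of 0.3 (1 tumour). Chromosome 3 passed in the authors' value table (4 tumours, permutation p = 0.0476), with centring on the mode (4 tumours, p = 0.0284), with normexp background correction (8 tumours) and at a threshold of 0.15 (7 tumours).

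The mean log2 ratio of the tumours differed from 0 on 3 chromosomes. Chromosome 3 had a mean of 0.19 (SD 0.13, n = 11), with 10 of 11 tumours above 0 (exact two-sided sign-flip permutation p = 0.00293, adjusted over 20 chromosomes 0.0260). Chromosome 15 had a mean of 0.14 (SD 0.12, n = 11), again with 10 of 11 tumours above 0 (exact permutation p = 0.00195, adjusted 0.0260). Chromosome 7 had a mean of -0.12 (SD 0.13, n = 11), with 10 of 11 tumours below 0 (exact permutation p = 0.00391, adjusted 0.0260). The counts above and below 0 depend on the centring of each array. In tumour 7 chromosomes 3 and 15 stood at 0.159 each, beside 0.141 to 0.149 on chromosomes 5, 17, 18 and 19, which had no gain call. Centring on the mode moved the median of that array by -0.158. With that centring in all arrays 5 chromosomes were called. Tumour 11 was the exception on chromosomes 3 and 7, with means of -0.026 and 0.016. With its ratios turned, 11 of 11 tumours were above 0 on chromosome 3 and below 0 on chromosome 7 (adjusted exact permutation p = 0.00977 for each), 9 of 11 were above 0 on chromosome 15 (adjusted p = 0.0260), and chromosome 12 passed as well (mean -0.07, adjusted p = 0.0488). In the labelled direction the sign was the same on each of the 3 slides, with means of 0.27, 0.12 and 0.19 for chromosome 3, of 0.27, 0.08 and 0.12 for chromosome 15, and of -0.15, -0.09 and -0.13 for chromosome 7. With slide as a random block in limma the adjusted p was 0.000963, 0.00341 and 0.0158 in the same order. The next chromosome was 12, with a mean of -0.07 and an adjusted permutation p of 0.107. None of the 20 chromosomes passed when tumour 1, 3, 4, 6, 8 or 9 was left out, with an adjusted p of 0.0521 for chromosomes 3, 15 and 7 in each of these cases. The chromosome 7 call was also lost with normexp (adjusted permutation p = 0.0846), without dim probes (0.0911), with the shared probe pattern removed (0.0651) and as a median over probes (0.0521). Dyes were not swapped, so a dye effect shared by the arrays could be part of these means and cannot be separated. The tumours were not shifted by equal amounts. They ranged from -0.026 to 0.39 on chromosome 3, from -0.0033 to 0.32 on chromosome 15 and from -0.37 to 0.016 on chromosome 7.

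**Figure D2:**
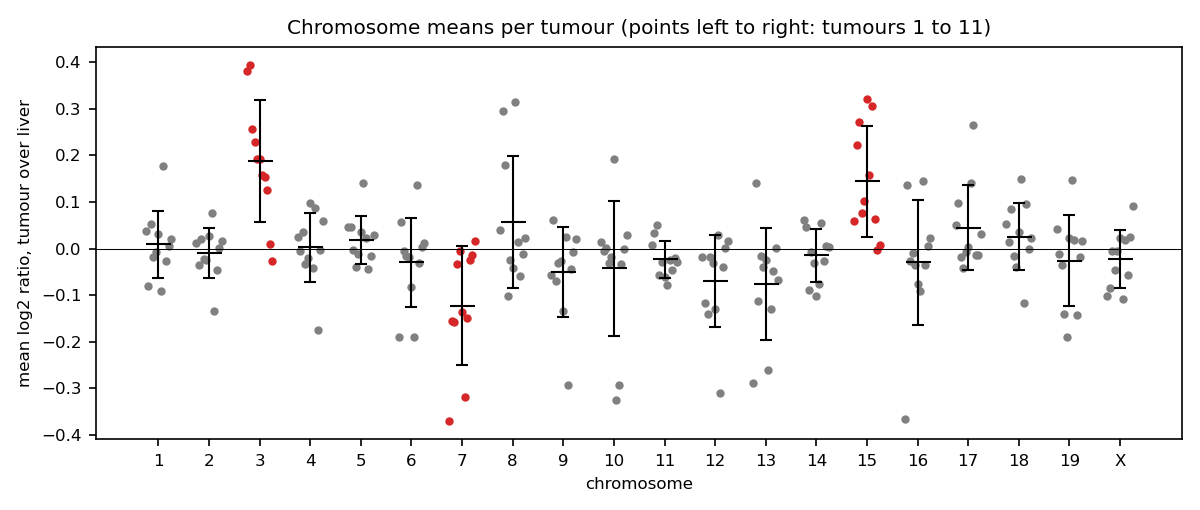
Mean log2 ratio of tumour over liver per chromosome, with 1 point per tumour and the mean over 11 tumours as a bar. Chromosomes 3 and 15 have 10 of 11 points above 0, with means of 0.19 and 0.14, and chromosome 7 has 10 of 11 points below 0, with a mean of -0.12; with the ratios of tumour 11 turned the shares are 11 of 11 for chromosomes 3 and 7 and 9 of 11 for chromosome 15.

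The locus of the model's own gene was read because the animals carry a mutant Pik3ca. Pik3ca (chromosome 3, 32340092 to 32363579, 4 probes) had a mean log2 ratio of 0.26 (SD 0.21, n = 11) and was above 0 in 11 of 11 tumours, from 0.01 in tumour 9 to 0.59 in tumour 1. The exact two-sided sign-flip permutation p was 0.000977, the smallest that 11 tumours can give. With the ratios of tumour 11 turned, its value of 0.033 became -0.033, leaving 10 of 11 tumours above 0 and a mean of 0.25 (exact permutation p = 0.00293). Called gains covered the gene in tumours 1, 2, 3 and 4, the shortest of them spanning 11.3 Mb. In tumour 7 the gene read 0.23, while chromosome 19, which had no call there, stood at 0.15, so part of this value may come from the centring. Relative to the probes within 5 Mb on both sides, Pik3ca had a mean of 0.04 (SD 0.09, n = 11), above 0 in 9 of 11 tumours (exact permutation p = 0.169), or 8 of 11 with tumour 11 turned (mean 0.025, exact permutation p = 0.414). No change of the gene beyond its surroundings was found.

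Changes of few genes were sought as segments of at most 10 Mb with a mean of at least 0.6 above or below 0. The search gave 38 gains and 11 losses, of which 17 gains lay in tumour 3, 9 gains and 1 loss in tumour 7, and 6 gains and 4 losses in tumour 8. Without tumour 3 there were 21 gains, and without tumour 1 or without tumour 8 there were 7 losses. With tumour 11 turned there were 37 gains and 12 losses. Normexp gave 100 gains, and a lower segmentation penalty gave 70 gains and 29 losses. At a height of 0.4 there were 61 gains and 32 losses. Losses were 28 with at least 5 probes per segment and 6 with at least 20.

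The strongest of these changes was a gain over Met on chromosome 6, present in 4 of the 11 tumours. The log2 ratio of Met (17420090 to 17515946, 12 probes) was 5.30 in tumour 8 (SD 0.22 over its probes), 3.38 in tumour 6 (SD 0.13), 3.02 in tumour 3 (SD 0.24) and 2.04 in tumour 7 (SD 0.23). The gained block ran from 16587960 to 18547874 in tumour 8, from 17264658 to 17955967 in tumour 6, from 15387562 to 17726880 in tumour 3 and from 17221391 to 19238673 in tumour 7. All 4 blocks covered the stretch from 17264658 to 17726880 (0.462 Mb, 43 probes), which holds probes of 5 annotated transcripts, namely Cav1, Met, Capza2, AK021346 and ENSMUST00000115420. In tumour 8 the block also held Wnt2, Asz1, St7, Cftr and Cttnbp2 at a similar height, with a segment mean of 5.57 at Cftr, and its highest part was a stretch of 6 probes from 16831634 to 16936310 with a mean of 6.32. Tumour 2 had a gain of 0.21 over 23.0 Mb that includes Met. The other tumours had no called change at Met.

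**Figure D3:**
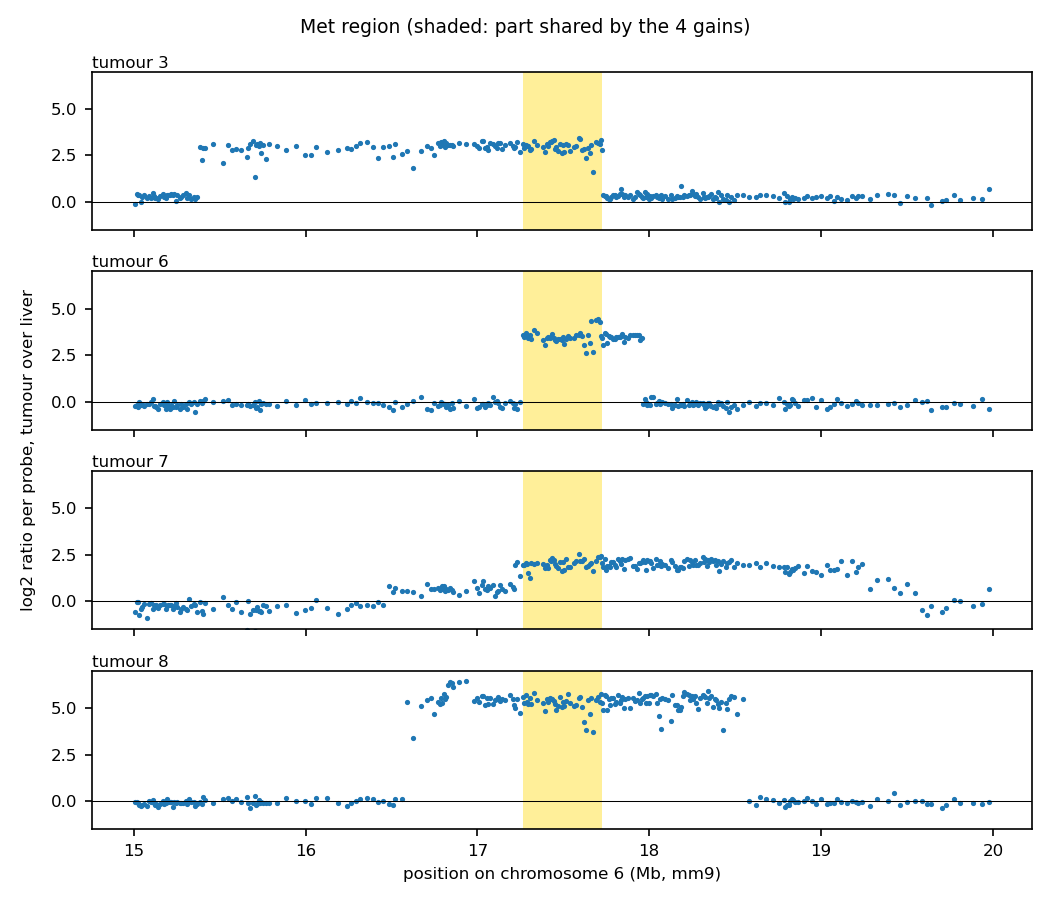
Log2 ratio of tumour over liver of single probes around Met on chromosome 6 in the 4 tumours with a focal gain, with position in Mb of build mm9 on the horizontal axis. The blocks share the stretch from 17264658 to 17726880, and the ratio of Met lies between 2.04 in tumour 7 and 5.30 in tumour 8.

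Further gains lay on the same chromosome in the same tumours. Tumour 6 had a second block from 31359959 to 32396660, with segment means of 3.26 and, over Plxna4, 3.18. Tumour 8 had a gain of 1.69 from 12244139 to 13264012, over Vwde and 5 other annotated transcripts. In tumour 7, chromosome 6 was lost as a whole but carried gained segments at Tes and Tfec (0.68), Fezf1 (0.79), Pot1a (0.67), and Gprin3 and Herc3 (0.83). A segment without annotated genes from 75871736 to 77050674 in tumour 7 had a mean of -0.98.

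Tumour 3 had a cluster of gains at the start of chromosome 9. The segment from 7347131 to 8367708 had a mean of 1.28 (SD 0.16 over 84 probes) and covered Birc2, Birc3 and Yap1. It was followed by gained segments of 1.27 to 1.78 up to position 15931394. On chromosome 3 the same tumour had gains from 35981649 to 61543273, with a peak of 1.12 over Pabpc4l and Pcdh10 and a mean of 0.63 over the segment that holds Foxo1. On chromosome 4 it had gains over Ptprd (0.61), Frem1 and Psip1 (0.73), Bnc2 (0.89) and Adamtsl1 (0.93). Tumour 2 had a gain of 0.72 over Nfib on chromosome 4 (SD 0.25 over 38 probes). Whether spots with a deposited LogRatio of 0 raised this mean was not tested.

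The focal losses included Nf1. In tumour 1 the segment from 78852316 to 79697736 on chromosome 11 had a mean of -0.998 (SD 0.21 over 67 probes) and covered Nf1 and 3 other annotated transcripts. A segment on the same chromosome from 38053719 to 39172248 had a mean of -0.98. Tumour 1 also had losses over Ap2a2 and Chid1 on chromosome 7 (-1.03) and over Clec4a2 and Clec4b1 on chromosome 6 (-0.69). In tumour 8 the losses lay over Skint4 (-0.75), Skint3 and Skint9 (-1.21) and Skint6 (-1.13) on chromosome 4, and from 116840011 to 117123306 on chromosome 12, inside the Igh locus (-1.02, over AK007918). The Skint losses of tumour 8 lay between longer losses of -0.31 and -0.28 on chromosome 4, and chromosome 12 was lost as a whole in that tumour. Tumour 7 had a gain of 0.34 from 111764589 to 112273763, over part of the same Skint stretch. The Skint genes belong to the families taken as variable between mouse strains, and 4 of the 11 focal losses lay over them, or 3 of 12 with tumour 11 turned. Tumour 11 had, in the labelled direction, a loss over Skint3 and Skint4 (-0.72) and gains over Prdx1 and Tesk2 (0.69) and over Nop14 and Grk4 (0.71). Inside the gain over Prdx1 and Tesk2, tumour 4 of the same slide had a loss of -0.59 (116298960 to 116427593). On chromosome 19 both arrays had a call from 38930621, at -0.33 in tumour 4 and 0.43 in tumour 11. The within-segment residuals of these arrays correlated at -0.61, so whether such calls are changes of the tumours stays open.

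With the settings chosen in advance, no gene was covered by calls in more tumours than random shifts of the calls along the genome gave. The test counted calls of 1 direction whatever their height, so it cannot judge the focal gains over Met by their height. The highest count was 5 tumours with a gain (one-sided permutation test with the maximum over genes, 1000 resamples, p = 0.0559). It was reached by 51 genes, of which 38 lay on chromosome 3 between 13474940 and 23831553, 7 on chromosome 15 between 86052036 and 88170354, and 6 on chromosome 6 around Met. The highest count of losses was 4 tumours (same permutation test, p = 0.464), reached by 7 genes on chromosome 7 between 3131659 and 3326916. Gained genes did pass without tumour 1 (13 genes), 4 (6 genes), 7 (45 genes) or 8 (38 genes), and with tumour 11 turned (51 genes). They also passed with normexp (1053 genes), a threshold of 0.15 (774), centring on the mode (256), without dim probes (86), with circular binary segmentation (79), in the authors' value table (73), at a lower or higher segmentation penalty (17 and 6) and after the GC fit (2), and lost genes passed at a threshold of 0.15 (116).

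Gene values were also tested against 0 with limma over 9300 genes with at least 3 probes. At an adjusted p below 0.05 and a mean of at least 0.1 above or below 0, 427 genes had higher and 214 had lower copy number in tumour than in liver, and 2135 genes had an unadjusted p below 0.05. Of the higher genes 257 lay on chromosome 3 and 128 on chromosome 15, and of the lower genes 118 lay on chromosome 7. The highest means on the called list were those of AK040671 (0.34, adjusted p = 0.0216), Hspa4l (0.33, adjusted p = 0.0193), AK158543 (0.33, adjusted p = 0.0415), Znhit6 (0.33, adjusted p = 0.0157) and Rnf13 (0.32, adjusted p = 0.0157), all on chromosome 3. The lowest were those of Ccdc81 on chromosome 7 (-0.42, adjusted p = 0.0239), Crebl2 on chromosome 6 (-0.36, adjusted p = 0.0193), and Ethe1, Apbb1 and Zc3h4 on chromosome 7 (-0.35, -0.35 and -0.34, adjusted p = 0.0157, 0.0193 and 0.0157). Met, with a mean of 1.32 (SD 1.84, n = 11), did not pass (adjusted p = 0.0815). Without tumour 3 the genes AK040671, Hspa4l, Ccdc81, Crebl2 and Apbb1 no longer passed (adjusted p from 0.0518 to 0.0542), nor did AK040671 without tumour 2 or Ccdc81 without tumour 4 or 7 (adjusted p up to 0.0600). AK158543 did not pass when any of tumours 1 to 9 was left out (adjusted p up to 0.0989). With the probe pattern shared by the arrays removed, a setting chosen after seeing the data, AK158543, Ccdc81, Crebl2, Ethe1 and Apbb1 did not pass, and the counts were 519 higher and 40 lower genes. The calls depended on single tumours, on centring and on the treatment of slides. With slide as a random block there were 762 higher and 738 lower genes, at an estimated correlation within slides of -0.11. Without tumour 3 the counts were 30 higher and 17 lower genes, without tumour 11 they were 830 and 781, with tumour 11 turned they were 828 and 851, and with centring on the mode they were 17 and 12. Leaving out tumour 1, 2, 4, 5, 6, 7 or 8 gave 157, 98, 134, 179, 63, 133 and 155 higher genes in that order, and 60, 72, 62, 101, 33, 55 and 70 lower genes.

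For 7 gene lists the median of the members was compared with 0 (exact two-sided sign-flip permutation test, adjusted over the lists), and none passed. The PI3K, AKT and mTOR pathway had a mean median of -0.01 (adjusted permutation p = 0.728). Of its 36 members read, 17 lay in a gain and 16 in a loss of at least 1 tumour, and 10 had no call. Pik3ca and Foxo1 (0.21, adjusted p = 0.0379 in limma), both on chromosome 3, passed the gene test over all genes, and 4 members passed when adjusted over the list alone. Rictor was gained in 4 tumours, each time with chromosome 15. The receptor tyrosine kinases had a mean median of 0.02 (adjusted permutation p = 0.434), with 8 members gained, 12 lost and 9 not called of 27, and 0 passed when adjusted over the list alone. The mean of the same list was 0.07, at percentile 99.9 of random lists, and Met alone had a mean of 1.32. Erbb2 was gained in tumours 2 and 8, with segment means of 0.24 and 0.33. The RAS and MAPK pathway had a mean median of -0.04 (adjusted permutation p = 0.434), with 10 members gained, 20 lost and 5 not called of 29. Rras2 on chromosome 7 was lower (-0.18, adjusted p = 0.0460 in limma), and 0 members passed when adjusted over the list alone.

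Amplified oncogenes and cell cycle genes had a mean median of -0.01 (adjusted permutation p = 0.728), with 18 members gained, 23 lost and 9 not called of 44, and 2 passed when adjusted over the list alone. Myc has no probe of its own under its name, and the interval between its neighbours A1bg and Pvt1 on chromosome 15 had a mean of 0.17 (SD 0.14, n = 11), with gains in tumours 2, 3, 6 and 8. Tumour suppressors had a mean median of -0.0038 (adjusted permutation p = 0.826), with 18 members gained, 19 lost and 11 not called of 44, and 0 passed when adjusted over the list alone. Trp53 was lost in tumours 7 and 8, and Nf1 was lost in tumours 1 and 7 and gained in tumour 8. Rb1 had no call, and Cdkn2a was gained in tumour 8. Genes of the mammary lineages had a mean median of -0.02 (adjusted permutation p = 0.592), with 15 members gained, 10 lost and 8 not called of 29, and 0 passed when adjusted over the list alone. Genes of common fragile sites had a mean median of 0.01 and a mean of -0.0049 (adjusted permutation p of the median 0.728), with 6 members gained, 7 lost and 6 not called of 18. Dpyd on chromosome 3 was higher (0.17, adjusted p = 0.0354 in limma) and was the 1 member that passed when adjusted over the list alone.

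The antigen receptor loci, which lose DNA in lymphocytes, were read to compare the lymphocyte content of tumour and liver. None of the 6 loci differed from 0 as a whole. The means were -0.03 for Igh, -0.09 for Igk, 0.05 for Igl, 0.0013 for Tcra/Tcrd, 0.02 for Tcrb and -0.0054 for Tcrg (n = 11, exact two-sided sign-flip permutation test, adjusted p between 0.750 and 0.940). Calls lay over the loci or parts of them. Longer losses covered all probes of Igk in tumours 1 and 7, of Igl in tumour 1 and of Tcrg in tumour 7, and reached into Igh in tumours 1 and 8 and into Tcrb in tumour 7. Longer gains covered all probes of Igl in tumour 2 and, in tumour 11 (0.34, from 52035530 to 54255755), 38 of the 94 probes of Tcra/Tcrd. Within Igh, a stretch from 116840011 was lost in tumours 3 (-0.41), 6 (-0.32) and 8 (-1.02), and a stretch from 114977008 in tumours 1 (-0.40) and 8 (-0.31). The second stretch stood near the level of longer losses beside it. These were at -0.28 and -0.34 in tumour 8, which lost chromosome 12 as a whole, and at -0.35 in tumour 1. Within Tcrb, tumour 8 had a gain of 0.62 from 41018389 to 41112757, and tumour 6 had a loss of -0.24 from 41144824 to 41290071. Relative to the probes within 5 Mb on both sides, 3 loci were above 0, namely Igh (0.06, SD 0.05, 9 of 11 tumours, adjusted exact permutation p = 0.0293), Tcrg (0.05, SD 0.06, 9 of 11 tumours, adjusted p = 0.0293) and Tcra/Tcrd (0.02, SD 0.02, 10 of 11 tumours, adjusted p = 0.0410). With tumour 11 turned none of the 6 loci passed relative to these probes, at 0.04 for Igh (8 of 11 tumours above 0, adjusted exact permutation p = 0.111), 0.02 for Tcrg (8 of 11, adjusted p = 0.668) and 0.02 for Tcra/Tcrd (9 of 11, adjusted p = 0.139).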

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

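The tests of GC content in tumour 11 and of the spread and correlation of strain-variable gene families were set before their results were seen, and the other tests of this part (Y probes, shared chromosome shifts, sign patterns, probe brightness and exchanged channels) were chosen only after the result was seen.

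Signal appeared on probes that no comparison used, the 122 probes of chromosome Y. Their mean log2 ratio over tumours was 0.50 (SD 0.38, n = 11), above 0 in 10 of 11 tumours, from -0.45 in tumour 11 to 0.92 in tumour 9 (exact two-sided sign-flip permutation p = 0.00488). With the ratios of tumour 11 turned its mean was 0.45, with 11 of 11 tumours above 0 and a mean of 0.58 (SD 0.21, exact permutation p = 0.000977, the smallest that 11 tumours can give). Of these probes 86.9% were not well above background on at least 1 array, against 19.8% of autosomal probes. The reason was not tested.

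The shared shifts of chromosomes 3, 15 and 7 had only technical explanations tested, since the design of 1 group gives no biological one. A probe pattern common to the arrays could not be judged by removing the first principal component of the within-segment residuals. These residuals average to 0 within each segment, so the removal can move a chromosome mean only through the re-centring of the array. After it the means of chromosomes 3 and 15 were 0.19 and 0.15 and past the test. For chromosome 7 the mean was -0.12 and the adjusted permutation p rose to 0.0651. The explanation by a shared probe pattern stays open for all 3 chromosomes. GC content was argued against for all 3, with means of 0.19, 0.15 and -0.12 past the test after the fit. A single slide was argued against as well, since the slide mean closest to 0 was 0.12, 0.077 and -0.090, while a dye effect stays open because dyes were not swapped.

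Of 100 sign patterns of the tumours, 1 gave as many called genes in limma as the real one, the real one itself, with 641 genes against 0 in the highest of the others. The patterns drawn did not include the one with tumour 11 alone turned, which gave 828 higher and 851 lower genes. The pattern with tumour 11 turned differs from the real one in 1 array, so its larger count does not show that random signs give such calls. As many calls as in the real pattern were rare among the patterns drawn. This argues against chance signs as the reason for the gene calls, which lie mostly on these 3 chromosomes. It does not judge technical explanations shared by the arrays.

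Tumour 11 ran opposite to several other arrays, with a correlation of within-segment residuals of -0.65 with tumour 9, and the design gives no biological explanation to test. Probe brightness is a candidate explanation, since the residuals of tumour 11 correlated at -0.480 with brightness measured on the other slides, against 0.603 for tumour 9 and 0.584 for tumour 4 of the same slide (correlations across probes, which are not independent replicates). GC content was argued against, because the correlation with tumour 9 was -0.696 after the fit. Exchanged channels stay open, since the chromosome means of tumour 11 correlated at -0.0525 with the mean of the other tumours, close to 0 either way, and few changes were called in tumour 11.

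Short changes at gene families that vary between mouse strains form the last pattern weighed, and no biological explanation was tested. A segment of 11 probes over Nlrp1b and Nlrp1c on chromosome 11 (70989862 to 71107103) was called as a gain in tumours 1, 2, 3 and 8. Its means were 0.47, 0.59, 0.51 and 0.45 in these tumours, -0.37 in tumour 6 and -0.36 in tumour 11. In tumour 8 this segment lay between losses of -0.28 and -0.27. Over Skint genes tumours 8 and 11 had losses (-1.21 and -0.72 over Skint3) and tumour 7 a gain (0.34). Those of tumour 8 lay between longer losses on chromosome 4. The signs of tumour 11 hold for the labelled direction. Tumour and liver DNA from animals that differ at these loci could give such values, although the labels give tumour and liver of the same animal. The spread of family genes in tumour 8 was 1.351 times the median of random draws of other genes, between the bounds set for and against this explanation. That spread, 0.190, lay inside the 0.121 to 0.359 of the draws, so it was no clear excess. In tumours 1, 2, 3, 7 and 11 it was 1.11, 0.972, 1.17, 1.13 and 0.870 times, below both bounds. The spread was just above the draws in tumour 1 (0.168 against an upper end of 0.166) and tumour 10 (0.174 against 0.172). It was below them in tumours 9 and 11. Family probes that read unevenly on every array stay open too, since the median correlation of family gene values between tumour 8 and the other low-noise arrays was 0.293, from 0.0817 in tumour 10 to 0.350 in tumour 3 (across genes, which are not independent replicates). The opposite signs at Nlrp1b go against that explanation for this segment, which was singled out after its values were seen.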

How the results depend on the processing

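Removal of the probe pattern, leaving out tumours 9 and 11 and turning the sign of tumour 11, alone or with the local baseline, were chosen only after the results were seen. No paired analysis was possible because the labels give 1 group, whose pairing of tumour and liver is already inside each array. The mean of Pik3ca stayed above 0 and past its test under normexp, mode centring, the GC fit, no dim probes, outlier spots kept, the authors' table and, without the local baseline, the 3 settings chosen later. With the local baseline it was above 0 but did not pass (0.041, or 0.025 with tumour 11 turned as well), and it ranged from 0.22 to 0.28 when single tumours were left out. Spots not well above background, up to 12.8% of an array (tumour 9), limit what dim probes show. Except where the construction gives it (fewer tumours, another threshold or minimum), the cause was not tested. With normexp background there were 330 gains and 71 losses, 22 whole-chromosome gains, 2 recurrent chromosome gains, 8 tumours with a gain of chromosome 3, 100 focal gains, 1053 recurrently gained genes and 813 higher genes. A lower penalty gave 516 gains, 734 losses, 70 focal gains, 29 focal losses and 17 recurrently gained genes, and a higher one 90, 66 and, for such genes, 6. A threshold of 0.15 gave 17 whole-chromosome gains, 2 recurrent gains, 7 tumours for chromosome 3, and 774 gained and 116 lost genes. A threshold of 0.3 gave 103 losses, 4 whole-chromosome gains, 6 whole-chromosome losses, 0 recurrent gains and 1 tumour for chromosome 15. Mode centring gave 2 recurrent gains, 4 tumours for chromosome 3, 256 recurrently gained genes, 5 called chromosomes, and 17 higher and 12 lower genes. The GC fit gave 0 recurrent gains, 4 tumours for chromosome 15 (permutation p = 0.0601) and 2 gained genes. The authors' table gave 4 tumours for chromosome 3, 3 for chromosome 15 and 73 gained genes, and circular binary segmentation gave 79. Leaving out dim probes gave 7 focal losses and 86 gained genes. Focal losses were 28 with at least 5 probes, 6 with at least 20 and 32 at a height of 0.4, where focal gains were 61. The chromosome 7 mean lost its call at -0.12 with normexp (adjusted p = 0.0846), without dim probes (0.0911), with the pattern removed (0.0651) and as a median (0.0521). Chromosome 15 was at 0.17 without tumours 9 and 11 (adjusted p = 0.0521) and at 0.27 on slide 1 alone. Slide as a random block gave 762 higher and 738 lower genes, a size limit of 0.2 gave 223 and 79, leaving out tumours 9 and 11 gave 828 and 665, and turning the sign of tumour 11 gave 828 and 851, with 51 recurrently gained genes. With the pattern removed there were 519 higher and 40 lower genes, and lower genes were 408 with at least 1 probe and 135 with at least 5.

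The local baseline called 3 antigen receptor loci and reversed Igh (0.055), Igk (0.014) and Tcrg (0.052). With tumour 11 turned as well it called 0 loci, with Igh and Tcrg still reversed (0.043 and 0.016). Tcrg was also reversed with normexp (0.020) and the GC fit (0.0023). Tcra/Tcrd was reversed by mode centring (-0.0092), the GC fit (-0.0030), the pattern removed (-0.0060), leaving out tumours 9 and 11 (-0.0040) and turning tumour 11 (-0.018). List medians were reversed with normexp for oncogenes (0.0087), tumour suppressors (0.0053) and mammary genes (0.019), and with the pattern removed for the PI3K pathway (0.015), tumour suppressors (0.0027) and mammary genes (0.032). Leaving out tumours 9 and 11 reversed tumour suppressors (0.00033), and mode centring and the list mean reversed fragile site genes (-0.0023 and -0.0049). None of these lists passed its test.

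Leaving out single tumours gave 6 to 10 whole-chromosome losses, 0 to 1 recurrent gains, 3 to 4 tumours for chromosome 15, 21 to 38 focal gains, 7 to 11 focal losses, 0 to 45 recurrently gained genes and 0 to 4 called chromosomes. The means ranged from 0.17 to 0.21 for chromosome 3, from 0.13 to 0.16 for chromosome 15 and from -0.14 to -0.10 for chromosome 7. Higher genes ranged from 30 without tumour 3 to 830 without tumour 11, and lower genes from 17 to 781. The sign changed for Tcra/Tcrd (-0.0090 to 0.012), Tcrg (-0.018 to 0.019), tumour suppressors (-0.012 to 0.0050) and fragile site genes (-0.0023 to 0.012).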

Other observations

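The test of breakpoints on chromosome 6 and the correlation with slide means removed were chosen only after the result was seen. The hypothesis was that breakpoints gather on the chromosome with the Met gain. Of the 4 tumours with that gain, 3 had more breakpoints on chromosome 6 than random placement gave (one-sided Monte Carlo test, 100000 draws). The draws placed each breakpoint independently, in proportion to the probes per chromosome, so breakpoints that come in clusters make these p-values too small. Tumour 7 had 29 against 4.10 expected (Monte Carlo p = 1e-05) and tumour 8 had 27 against 7.89 (Monte Carlo p = 1e-05). In both cases this is the smallest p the draws can give. Tumour 6 had 23 against 9.22 (Monte Carlo p = 5e-05). Tumour 3 had 10 against 6.57 (Monte Carlo p = 0.123), and its breakpoints gathered on chromosome 4 instead, with 25 against 6.39. The prediction was that all 4 tumours would pass, so the test left the hypothesis open, and the segments that form the Met gain are themselves among the breakpoints counted.

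The noise SD of the arrays went with the share of altered autosomal probes by rank but not by Pearson's r. Over the 11 tumours Pearson's r was -0.564 (permutation p = 0.0654) and Spearman's rho was -0.661 (permutation p = 0.0309), and without tumours 9 and 11 neither passed (n = 9, r = -0.351, exact permutation p = 0.348, and rho = -0.483, exact permutation p = 0.194). With the slide means removed, r was -0.642 (exact permutation within slides, p = 0.0304) and rho was -0.667 (p = 0.0538), and without tumours 9 and 11 they were -0.562 (n = 9, exact permutation p = 0.198) and -0.575 (p = 0.177). The relation thus did not pass by both measures in either form. Without tumours 9 and 11 the correlations kept their sign but were weaker, and fewer tumours also lower the power. The penalty per breakpoint rises with the noise variance of the array, so changes are harder to call in a noisier array. A negative relation is thus partly built into the calling and does not show that tumours on noisier arrays are less altered. Whether the relation rests on tumours 9 and 11 stays open. Single slides of 3 to 4 arrays hold too few samples for a correlation of their own.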
